A study of Mus musculus with 8 samples.

How the data were processed

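The data are ATAC-seq peak lists from 8 libraries of sorted mouse SMARTA CD4 T cells, 2 each of Tfh and non-Tfh cells after infection (spleen) and after immunization (draining lymph node). Reads had been aligned with BWA to mm10 and peaks called with MACS2, per the submitters' processing notes. Versions and options are not given in the sources used here. Each library had its own list of called peaks with 10 columns and no header, and an interval with several summits is repeated once per summit. The deposited score is 10 times the −log10 q value, as checked on the values. The deposited fold is the ratio of signal at the summit to the library's own local background. The −log10 p and −log10 q values are the authors', computed within each library, and the smallest −log10 q was 1.30 in each list. These values are not scaled between libraries, so they were used here to rank or filter peaks within their own list and, apart from that, only for the background described below.

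The lists held 46565 to 60753 lines, or 38096 to 48853 intervals after lines with the same interval were joined. Reads were not used here, and the depth of each library is unknown. A background pileup was solved for weak summits (−log10 p up to 20) from their fold and −log10 p under a Poisson model, and was 1.76 to 2.15 per library. Chromosomes 1 to 19 and X were compared, and chromosome Y (22 to 25 intervals per library) was left out. Intervals of all libraries that overlapped by at least 1 bp were merged into 64219 regions, and a library counts as called in a region where any of its intervals overlaps it. Within a comparison, a region is accessible when called in both libraries of either group, and specific when also called in neither library of the other group.

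Regions were given to protein-coding genes by gene extents, since the reference used here holds no strands, exons or sequence. A region whose midpoint lay in a gene body went to that gene, or with several to the one with the nearest end, and any other region to the nearest gene within 100 kb. This replaced the planned distance to the transcription start site. Of the regions, 61127 (95.19%) received a gene, and 15304 of 21631 genes had regions. A region is near a gene end when it lies within 1 kb of either end of a gene. Motif content was planned for 25 motifs and not run for lack of sequence.

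The comparisons, tests and rule for named genes were set before the data were examined. Tfh and non-Tfh cells were compared within each stimulus, the stimuli within each cell type, and both factors over all 8 libraries. Specific regions of 2 against 2 libraries were set beside the 2 crossed splits of the same libraries, and those of 4 against 4 beside all 35 splits. Fisher's exact test was applied to each region for 4 against 4, with Benjamini-Hochberg adjustment. Jaccard indices were tested with a pseudo-F statistic and exact permutation of the libraries, two-sided. The 20 lists of genes hold 364 genes found in the reference, counted once per list, and 338 distinct genes. The shift of a list is the percentage of its accessible regions specific to the first group minus that specific to the second. It was set against 10000 random lists of genes matched on the number of regions, and the two-sided p was adjusted over 76 tests with a threshold of 0.05. The difference of the Tfh contrast between infection and immunization was tested in the same way for 19 lists, a test added after the data were seen.

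Genes named in each comparison are 14 lineage genes, the 6 genes per direction with the largest net number of specific regions, and up to 4 members of each list that passed. A single gene that this rule names is not reported here. Regions named are the 3 per direction with the highest percentile of −log10 q within the list, taken as the lower of the libraries, and 5 per direction over both stimuli.

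Alternatives were a −log10 q minimum of 5, the 20000 best peaks of each library, peaks covering at least 50% of a region, windows of 501 bp around summits, leaving out each library in turn, a distance of 20 kb, gene bodies with 10 kb around them, distal regions only and a replicate block. Added after the data were seen were the 38000 best peaks of each library, and a margin that asks for a −log10 q of at least 5 in both libraries of one group and no peak in the other. A background of the overlap without regions called in all libraries was added too.

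The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and were tested on simulated data. With 1000 of 64219 regions made specific and detected in 90% of libraries, the share recovered was 81.8% for Tfh against non-Tfh after infection, 82.4% after immunization, 80.0% for infection against immunization in Tfh and 81.3% in non-Tfh, where 81.0% is the product of detection in both libraries. Of 200 random lists of 20 genes per comparison, 3.0, 4.5, 1.5 and 1.5% had p under 0.05 in this order. With 20% of their regions made specific, 51.5, 90.0, 75.5 and 41.5% did, among 14198, 13772, 14239 and 13923 genes with accessible regions.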

Results

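Chromatin accessibility was profiled by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open chromatin, in mouse SMARTA CD4 T cells. SMARTA cells carry a transgenic T cell receptor that recognises a glycoprotein epitope of lymphocytic choriomeningitis virus (LCMV). Donor cells marked by CD45.2 had been transferred into CD45.1 mice, which were then either infected with LCMV or immunized with protein. On day 5, T follicular helper (Tfh) cells, which help B cells in follicles, and non-Tfh cells, which the labels also call Th1, were sorted from spleen after infection and from draining lymph nodes after immunization. The 4 groups had 2 libraries each, 8 in all, and nothing in the labels says whether the libraries of a group came from separate animals, so the spread between them may be technical. Infection and spleen, and immunization and lymph node, always went together. Peaks had been called in each library on its own, and the lists held 38096 to 48853 intervals covering 27.57 to 34.45 Mb. Read counts and depth are not given by the lists. The longest lists were those of infection Tfh, with 46195 and 48853 intervals, and the shortest that of infection non-Tfh replicate 2, with 38096.

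Merging the 8 lists gave 64219 regions with a median length of 678 bp. Of these, 25270 were called in all 8 libraries and 10876 in a single library. A region is called accessible in a group when both of its libraries had a peak there, and specific to a group when both of its libraries and neither library of the other group had one. Of the 25270 regions called in every library, 38.6% lay within 1 kb of an end of a protein-coding gene (Wilson 95% interval 38 to 39.2%). Among the 19240 regions specific in at least 1 of the 4 pairwise comparisons this share was 6.13% (5.80 to 6.48%), and the others lay inside gene bodies or between genes. The intervals cover counting error over regions only.

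Libraries were compared first by the share of called regions they had in common, which asks whether cell type or stimulus orders the accessible genome. Infection non-Tfh cells stood apart from the 3 other groups. Their libraries shared a mean Jaccard index of 0.612 with immunization Tfh, 0.612 with immunization non-Tfh and 0.636 with infection Tfh, against 0.808 between their own replicates. Infection Tfh cells shared more with the immunization groups (0.677 with Tfh, 0.676 with non-Tfh) than with infection non-Tfh cells, where the highest of 4 library pairs was 0.649 and the lowest pair with either immunization group was 0.659. Immunization Tfh and non-Tfh cells were close, at 0.756 (range 0.744 to 0.768 over 4 pairs), below the 0.794 and 0.817 of their own replicates. In an exact permutation test over the 35 splits of the 8 libraries into 4 and 4, stimulus gave a pseudo-F of 3.65, the highest of all splits (two-sided p = 0.0286, the smallest this design allows). These splits treat the 8 libraries as independent, and only 3 of them keep the replicates of every group together. Cell type gave a pseudo-F of 1.58, and 4 of the 35 splits were as large (exact permutation p = 0.114).

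**Figure D1:**
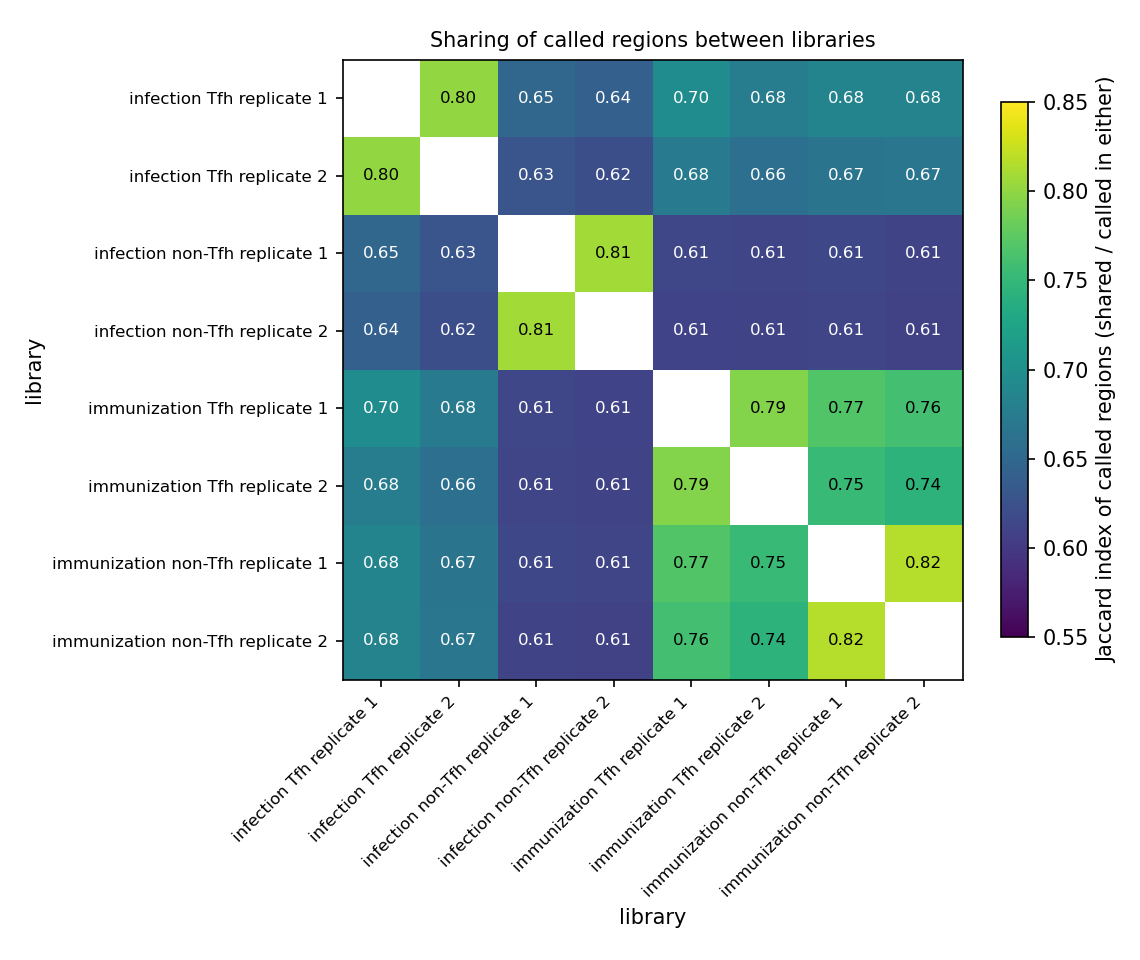
Jaccard index of called regions (regions called in both libraries over regions called in either) for each pair of the 8 libraries, with the libraries on both axes. Replicates of a group share 0.79 to 0.82, infection non-Tfh shares about 0.61 with both immunization groups, and the immunization groups share 0.74 to 0.77 with each other.

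The first comparison asks which chromatin separates Tfh from non-Tfh cells after infection. Infection Tfh cells had 8046 specific regions (17.7% of the 45462 accessible in either group) and non-Tfh cells 2374 (5.22%). The largest excess of Tfh-specific regions lay at Lpp, a LIM-domain adhesion protein gene next to Bcl6, with 22 Tfh-specific and 3 non-Tfh-specific regions of 43, and at Inpp4b, a phosphoinositide phosphatase gene, with 17 and 2 of 38. Genes of the Th1 and cytotoxic effector program shifted towards non-Tfh cells, with 36 non-Tfh-specific and 14 Tfh-specific regions of 230. Both crossed splits of the same 4 libraries, which pair a Tfh with a non-Tfh library on each side, gave 745 and 732 specific regions in total, against 10420 for the real split, a 14.0-fold excess over the larger. With 2 against 2 libraries no exact test can go below p = 0.333, so no region is called significant on its own.

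Further genes with most infection Tfh-specific regions were Rad51b, a DNA repair gene (13 Tfh-specific, 1 non-Tfh-specific), Hdac4, a histone deacetylase gene (12 and 1), Nav2 (11 and 0) and Sox5, which encodes an HMG-box transcription factor (11 and 0). Ranking by net number, here and in the other comparisons, favours long genes with many accessible regions, such as Rad51b with 43. On the non-Tfh side stood Cmklr1, the chemerin receptor gene, all of whose 7 accessible regions were non-Tfh-specific, followed by Gas7 (6 of 8), Niban1 (6 of 14), Nmnat2 (5 of 10), Tmem163 (5 of 11) and Gramd3 (5 of 19). Of the lineage genes, Tcf7, which encodes TCF-1, had 3 Tfh-specific and 0 non-Tfh-specific regions, Bcl6, the repressor that Tfh differentiation requires, had 2 and 0, and Cxcr5, the follicle-homing receptor gene, had 1 and 0. Il12rb2, a subunit of the interleukin-12 receptor, had 3 and 1. Ifng had 0 and 3, Tbx21, the gene of the Th1 factor T-bet, had 0 and 2, and Il2ra, Il21 and Pdcd1 each had a net of 1 region on the non-Tfh side. Lef1 had 3 in each direction, Prdm1, the gene of the Bcl6 antagonist Blimp-1, had 1 in each, as did Id2 and Gzmb. No region was assigned to Cxcr6. Singled out after their values were seen, the Tfh-specific regions near Bcl6 lay between genes at chr16:23993545-23994055 and chr16:24016643-24017235 (mm10), 4934 and 28073 bp beyond the gene. They were called in no immunization library, nor was the Tcf7 region at chr11:52320397-52320843. The Cxcr5 region (chr9:44554968-44556283) and the Tcf7 regions at chr11:52249310-52252204 and chr11:52283914-52284506 were also called in both libraries of each immunization group. These regions were thus missing from infection non-Tfh cells rather than particular to Tfh cells.

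Of the 30 Th1 and cytotoxic effector genes with regions, 16 had more non-Tfh-specific regions, 3 more Tfh-specific ones and 11 neither. The list's net shift was -9.57% of its accessible regions, against a mean of 11.68% for 10000 random lists matched on the number of regions per gene (permutation p = 0.0001, the smallest they can give; Benjamini-Hochberg adjusted p = 0.0019 over 76 tests of lists and comparisons). Ccr2, Il18rap, Klrg1 and Ifng had 3 non-Tfh-specific regions each. NK cell markers also shifted towards non-Tfh, with 6 of 24 regions non-Tfh-specific and 0 Tfh-specific (shift -25.0%, random mean 13.66%, adjusted permutation p = 0.043), among them 2 at Klrb1c and 1 each at Gzmc, Klra8 and Klre1. The Tfh program did not pass, with 45 Tfh-specific and 19 non-Tfh-specific regions of 244 and a shift of 10.66%, close to the random mean of 12.11% (adjusted permutation p = 0.98). B cell markers had 9 Tfh-specific and 0 non-Tfh-specific regions of 23 and did not pass (adjusted permutation p = 0.11). The strongest Tfh-specific regions by the caller's own ranking within each list lay in the gene bodies of Stim1 (chr7:102322016-102322934), Eipr1 (chr12:28833971-28834997) and Hsdl1 (chr8:119569545-119570478), at or above percentiles 92.0, 90.4 and 87.5 of −log10 q in both libraries. All 3 were also called in the 4 immunization libraries. The strongest non-Tfh-specific ones lay on chromosome 10 with no gene assigned (chr10:96350559-96351517), in the Ago2 gene body (chr15:73146760-73147262) and 5874 bp from Ccr2 (chr9:124114654-124115374), and were called in no other group.

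The excess of infection Tfh-specific regions shrank with equally long lists. With the 38000 best peaks of every library, an alternative added after the data were seen, 4527 regions were Tfh-specific and 4050 non-Tfh-specific, and with the 20000 best 2175 and 2131. The NK call held in 7 of 13 alternatives, with shifts of -34.78 to 0.0% and adjusted permutation p up to 1.0.

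**Figure D2:**
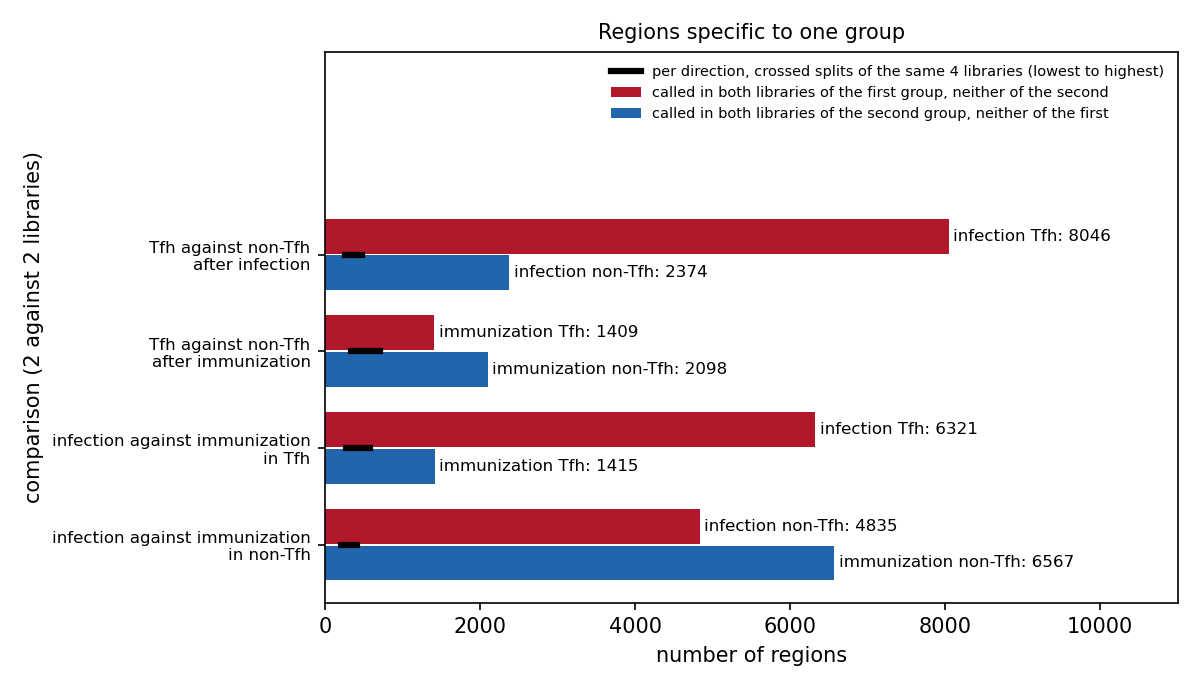
Number of regions called in both libraries of one group and in neither library of the other, for each pairwise comparison of 2 against 2 libraries. Black lines span the lowest to highest count per direction over the 2 crossed splits of the same 4 libraries (210 to 711 over all comparisons), below each real count, the lowest of which is 1409.

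The same contrast was made after immunization. Tfh cells had 1409 specific regions (3.58% of 39352) and non-Tfh cells 2098 (5.33%). Lpp again led the Tfh side, with 9 Tfh-specific and 1 non-Tfh-specific regions of 34. Regions at B cell genes formed the clearest group on this side: 10 of 14 B cell marker genes had Tfh-specific regions, among them the B-lineage factor genes Ebf1 and Pax5 and the Fc receptor-like gene Fcrla with 3 each and the B cell linker gene Blnk with 2. Crossed splits gave 1034 and 1046 specific regions in total, so the real total of 3507 exceeded the larger by 3.35-fold, the smallest excess of the 4 comparisons. No exact test on these 4 libraries can go below p = 0.333.

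Besides Lpp, the genes with most immunization Tfh-specific regions were Kcnh1, a potassium channel gene (5 of 5), Rapgef5, an exchange factor gene for Rap GTPases (5 of 12), Lyn, a Src-family kinase gene of B and myeloid cells (4 of 5), Bcl11a, a zinc-finger factor gene active in B cells (4 of 7), and Smco4 (4 of 11). The non-Tfh side was led by Kcnq5 (6 of 15), Foxp1, a factor gene linked to T cell quiescence (6 of 55), Prkca (5 of 27), Inpp4b (7 against 2 Tfh-specific, of 41), F13a1 (4 of 14) and Exoc2 (4 of 21). Inpp4b thus had its excess on the Tfh side after infection and on the non-Tfh side after immunization, a difference that was not tested. Few specific regions lay at the lineage genes. Cxcr5, Tcf7, Lef1, Tbx21, Prdm1, Id2, Il2ra and Il12rb2 had 0 in either direction. Bcl6 and Pdcd1 had 1 non-Tfh-specific region each, Gzmb had 2 non-Tfh-specific ones, Ifng had 2 Tfh-specific ones and Il21 had 1. A region called in both groups may still differ in signal, which was not compared between libraries.

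B cell markers had 18 Tfh-specific and 1 non-Tfh-specific regions of 40 (shift 42.5%, random mean -1.58%, permutation p = 0.0001, the smallest possible; adjusted p = 0.0019). Myeloid and dendritic cell markers had 8 and 2 of 45 (shift 13.33%, adjusted permutation p = 0.048), with 2 Tfh-specific regions at Flt3 and 1 each at Adgre1, Mpeg1 and Cd14. The Tfh program had 9 Tfh-specific and 8 non-Tfh-specific regions of 230 (shift 0.43%, adjusted permutation p = 0.52), and the Th1 and cytotoxic effector program 6 and 8 of 151 (shift -1.32%, adjusted permutation p = 0.98). NK cell markers and stromal and endothelial markers had 0 specific regions in either direction, of 15 and 13. The strongest Tfh-specific regions lay 2080 bp from Rapgef5 (chr12:117761440-117762194), in Tmem29 (chrX:150413078-150414113) and in Mcf2l (chr8:12936995-12937892), and all 3 were also specific to Tfh after infection. The strongest non-Tfh-specific regions lay in Gm31493 (chr1:159999225-159999768), 3014 bp from Xkr5 (chr8:18953857-18954381) and on chromosome 6 with no gene assigned (chr6:3165959-3166565). At Ms4a1, the gene of the B cell antigen CD20, a region 195 bp from the gene (chr19:11265936-11266752), singled out after its values were seen, was called in both immunization Tfh libraries and in no other library.

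With the 38000 best peaks of each library the counts were 1615 for Tfh and 1519 for non-Tfh cells, so the split did not keep its direction. The myeloid and dendritic call was lost in all 13 alternatives, with shifts of 2.63 to 14.29%, and the B cell shift was 0.0% with the 20000 best peaks per library, a setting that drops the weak peaks of these regions.

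**Figure D3:**
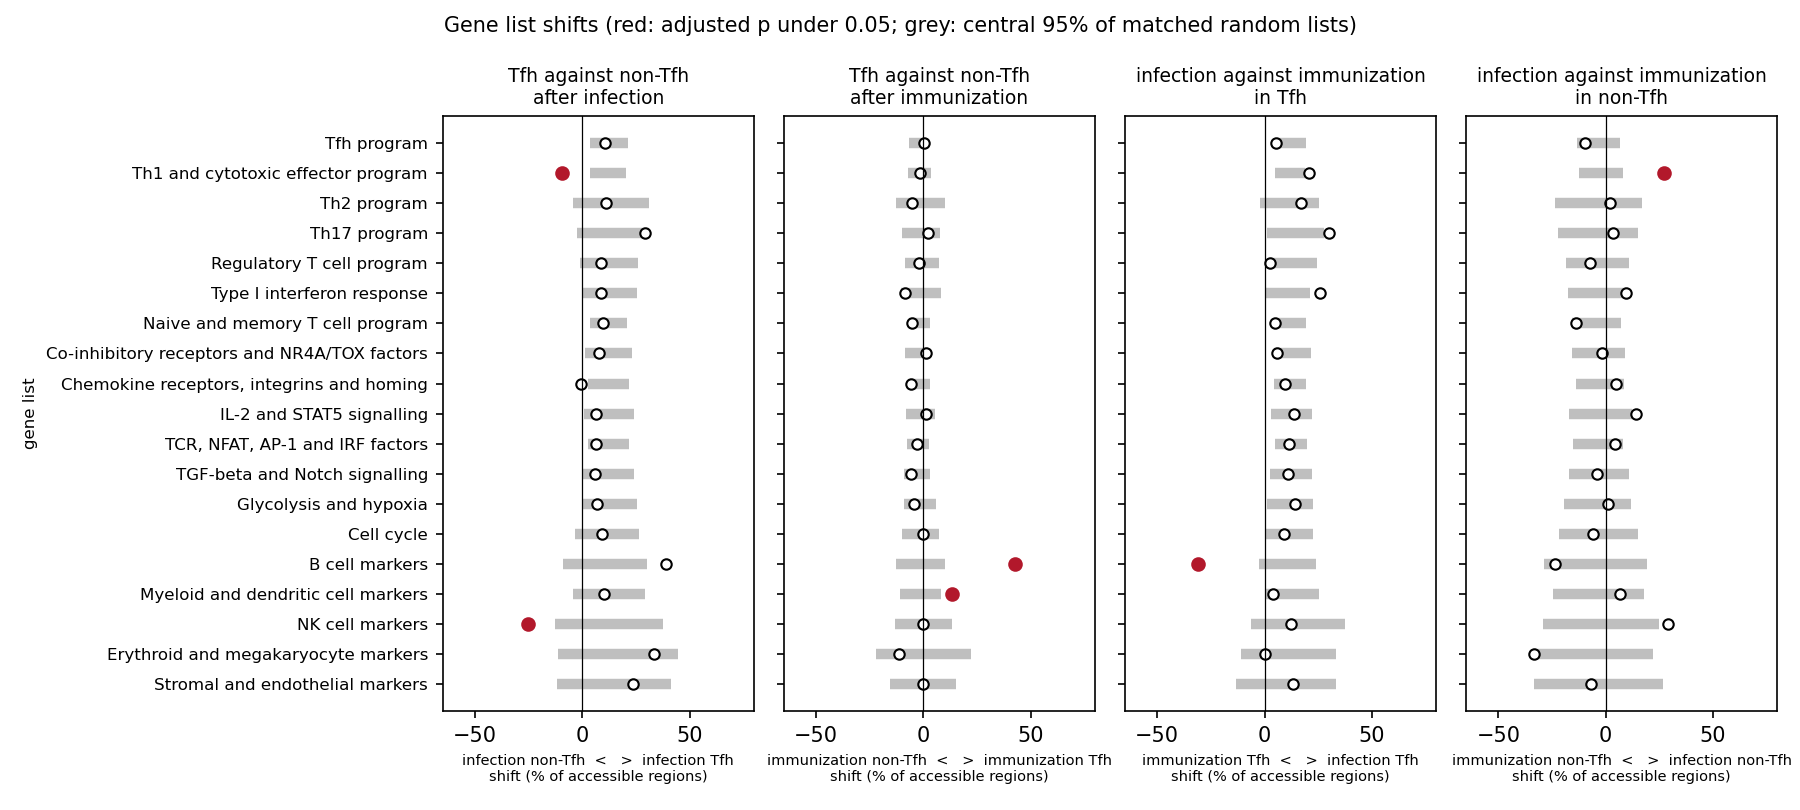
Net shift of each tested gene list in each pairwise comparison, as the percentage of accessible regions specific to the first group minus that specific to the second. Circles are the lists (red with adjusted permutation p under 0.05), grey bars the central 95% of 10000 matched random lists; the Th1 and cytotoxic effector program lies at -9.57% between the infection groups and at 27.23% between the non-Tfh groups, and B cell markers at 42.5% between the immunization groups.

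The third comparison sets infection against immunization within Tfh cells. Infection Tfh cells had 6321 specific regions (14.3% of 44336) and immunization Tfh cells 1415 (3.19%). Infection-specific regions were most numerous at Rora, the gene of the nuclear receptor RORα (14 of 33), Prkca, a protein kinase C gene (13 against 1, of 35), Atxn1 (12 against 1, of 40), Rad51b (13 against 2, of 44), Atrnl1 (9 of 16) and the RUNX factor gene Runx2 (9 of 27). Prdm1 had 6 infection-specific regions of 14, Tbx21 4 of 6 and Gzmb 3 of 6, each with 0 on the immunization side. The real total of 7736 exceeded the crossed splits (915 and 852) 8.45-fold.

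Of the other lineage genes, Bcl6 and Il12rb2 had 2 infection-specific regions and 0 immunization-specific ones, Il21, Tcf7 and Id2 had 1 and 0, Lef1 had 2 and 1, Il2ra had 1 and 1, Ifng had 1 and 2, and Cxcr5 and Pdcd1 had 0 in either direction. The immunization side held Bcl11a (4 of 7) and, with 3 regions each, Ebf1, Tgtp1, Speer4c, Gm51572 and Gm40892. B cell markers shifted towards immunization, with 16 immunization-specific and 3 infection-specific regions of 42 (shift -30.95%, random mean 10.85%, adjusted permutation p = 0.0019). Ebf1 had 3 of these, and Bank1 and Fcrla 2 each. This call shares the immunization Tfh libraries with the call above and is not independent of it. The type I interferon response had 16 infection-specific and 0 immunization-specific regions of 62, at 12 of 27 genes, and did not pass (shift 25.81%, adjusted permutation p = 0.084). The Th1 and cytotoxic effector program had 45 and 5 of 193 (shift 20.73%, random mean 11.59%, adjusted permutation p = 0.097) and did not pass, though it passed towards infection in 6 alternatives (adjusted permutation p = 0.0074 to 0.044). The Tfh program had 24 and 11 of 244 and did not pass (shift 5.33%, random mean 12.53%, random lists 6.06 to 19.43%, adjusted permutation p = 0.18). Its shift lay below this range, so against random lists it leaned towards immunization, although more of its regions were infection-specific. The list passed towards immunization without infection Tfh replicate 2 (shift 3.57%), where a single library stood for infection Tfh. The strongest infection-specific regions lay 24954 bp from Lrrc8d (chr5:105839801-105840536), in Bace2 (chr16:97401554-97402797) and 24872 bp from Gpc1 (chr1:92806312-92807234). All 3 were also called in both infection non-Tfh libraries. The strongest immunization-specific ones lay 12501 bp from Parp11 (chr6:127433926-127434732), in Gabrb1 (chr5:71903251-71904091) and on chromosome 2 with no gene assigned (chr2:118007899-118008512).

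With the 38000 best peaks of each library, 3319 regions were infection-specific and 2746 immunization-specific, and with the 20000 best 1480 and 1250. The B cell call ended with a −log10 q minimum of 5 (adjusted permutation p = 0.15), with the 20000 best peaks (0.74) and with a margin between called and not called (0.17). Over 13 alternatives the adjusted p was 0.0019 to 0.74.

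Within non-Tfh cells, the stimuli differed more than in any other pairwise comparison. Infection non-Tfh cells had 4835 specific regions (11.2% of 43140) and immunization non-Tfh cells 6567 (15.2%), a total of 11402 against 598 and 619 in the crossed splits, 18.4-fold. The Th1 and cytotoxic effector program shifted towards infection, with 71 infection-specific and 10 immunization-specific regions of 224. At Foxp1, 24 regions of 57 were immunization-specific and 2 infection-specific, and at Inpp4b 20 and 2 of 41.

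Infection-specific regions were most numerous at Runx2 (12 against 2, of 29), Rbm47 (10 of 20), Lrrk1 (9 of 15), Gas7 (8 of 8), Niban1 (8 of 14) and Prdm1 (8 of 16). The immunization side also held Maml2, a Notch coactivator gene (13 against 1, of 26), Ldlrad4 (12 of 17), F13a1 (10 of 14) and the clock factor gene Npas2 (10 of 14). Of the 30 Th1 and cytotoxic effector genes with regions, 21 had more infection-specific regions, 0 more immunization-specific ones and 9 neither (shift 27.23%, random mean -2.03%, permutation p = 0.0001, the smallest possible; adjusted p = 0.0019). Prdm1 had 8 of them, the RUNX factor gene Runx3 6, the killer-lectin receptor gene Klrg1 5 and Tbx21 4. Il2ra had 4 and 0, Ifng 5 and 1, Il21 3 and 0, Id2 3 and 1, Gzmb 2 and 0, and Il12rb2 and Pdcd1 2 and 1. Tcf7 had 1 infection-specific and 3 immunization-specific regions, and Bcl6, Cxcr5 and Lef1 had 0 and 1. The naive and memory T cell program had 66 immunization-specific and 25 infection-specific regions of 298 and did not pass (shift -13.76%, adjusted permutation p = 0.3), nor did IL-2 and STAT5 signalling with 23 infection-specific and 7 immunization-specific regions of 112 (shift 14.29%, adjusted permutation p = 0.18). The strongest infection-specific regions lay 21671 bp from Nsmaf (chr4:6476170-6476851), 17266 bp from Trerf1 (chr17:47123182-47124169) and in Zbtb38 (chr9:96713983-96714655). The strongest immunization-specific regions lay in Eipr1 and Hsdl1, at the positions given above, and 14444 bp from Il1b (chr2:129385160-129386056). All 3 were called in every library except those of infection non-Tfh. With the 38000 best peaks per library the counts were 5384 and 5517, and with the 20000 best 2889 and 2785, which turned the direction.

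Over both stimuli, 318 regions were called in all 4 Tfh libraries and no non-Tfh library, and 61 the other way round. The 5 strongest Tfh regions by the lowest of 4 percentiles were the ones 2080 bp from Rapgef5 and in Tmem29 named above, a region on chromosome 12 with no gene assigned (chr12:77666327-77667274), another inside Rapgef5 (chr12:117712375-117713058) and one in Tamm41 (chr6:115007737-115008183). The strongest non-Tfh regions lay 8930 bp from Olfr1423 (chr19:12026532-12027223), 4019 bp from Cmas (chr6:142752512-142752821), on chromosome 7 with no gene assigned (chr7:58451952-58452367), in Arhgap26 (chr18:39140494-39141969) and 1684 bp from Zeb2, a zinc-finger repressor gene (chr2:44981613-44982043). Over both cell types, 1476 regions were called in all 4 infection libraries and no immunization library, and 596 the other way round. With equally long lists this direction turned, to 538 for infection and 629 for immunization with the 20000 best peaks, and 1033 and 1041 with the 38000 best. Fisher's exact test of 4 against 4 gave p = 0.0286, the smallest it can give, for each of these 379 cell-type and 2072 stimulus regions. These are too few at that p to pass Benjamini-Hochberg adjustment over 64219 regions. That 0 passed thus follows from these counts and the smallest p of the test, and says nothing about single regions.

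The last comparison asks whether the same regions separate Tfh from non-Tfh cells under both stimuli. The 318 regions Tfh-specific after infection and after immunization compare with 226 for independent sets of these sizes among 50062 accessible regions, a ratio of 1.40. Regions non-Tfh-specific under both stimuli numbered 61 against 99.5 expected. Regions Tfh-specific after infection but non-Tfh-specific after immunization numbered 252 against 337, and the opposite pattern 10 against 66.8. The planned reference was the 16 overlaps between crossed splits within the stimuli, which held 0 to 11 regions. Their ratios were 0.0 to 2.80 with a median of 1.77, and 13 of the 16 were at least as large as the real ratio. The real ratio thus did not exceed this reference, though each of these overlaps rests on few regions. The expected number depends on the background. Without the 25270 regions called in all libraries, a choice made after the data were seen, 457 shared Tfh-specific regions would be expected and the ratio is 0.695. The ratio there was 0.304 for regions non-Tfh-specific under both stimuli. It was 0.37 for regions Tfh-specific after infection but non-Tfh-specific after immunization, and 0.0741 for the opposite pattern. All ratios are thus lower with this background, and neither an excess nor a lack is claimed. Of the 8046 infection Tfh-specific regions, 2748 (34.2%) were called in all 4 immunization libraries and 2453 (30.5%) in none. Of the 2374 infection non-Tfh-specific regions, 81 (3.41%) were called in all 4 and 1849 (77.9%) in none. Without immunization Tfh replicate 1 the ratio for shared Tfh-specific regions was 1.04, and with the 20000 best peaks per library it was 2.29.

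Bcl6 and Lpp are neighbours on chromosome 16, and the interval from the start of Bcl6 to the far end of Lpp (chr16:23965050-24992578, 1028 kb) was looked at as a whole after the Lpp counts had been seen. It held 89 regions. After infection 28 of 58 accessible regions were Tfh-specific and 3 non-Tfh-specific, and after immunization 11 of 50 were Tfh-specific and 2 non-Tfh-specific. Inside Lpp, regions at chr16:24593343-24594135, chr16:24850387-24851174, chr16:24925254-24926110 and chr16:24933491-24934133 were called in all 4 Tfh libraries and in no non-Tfh library. Between the genes the same held at chr16:24171827-24172410.

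**Figure D4:**
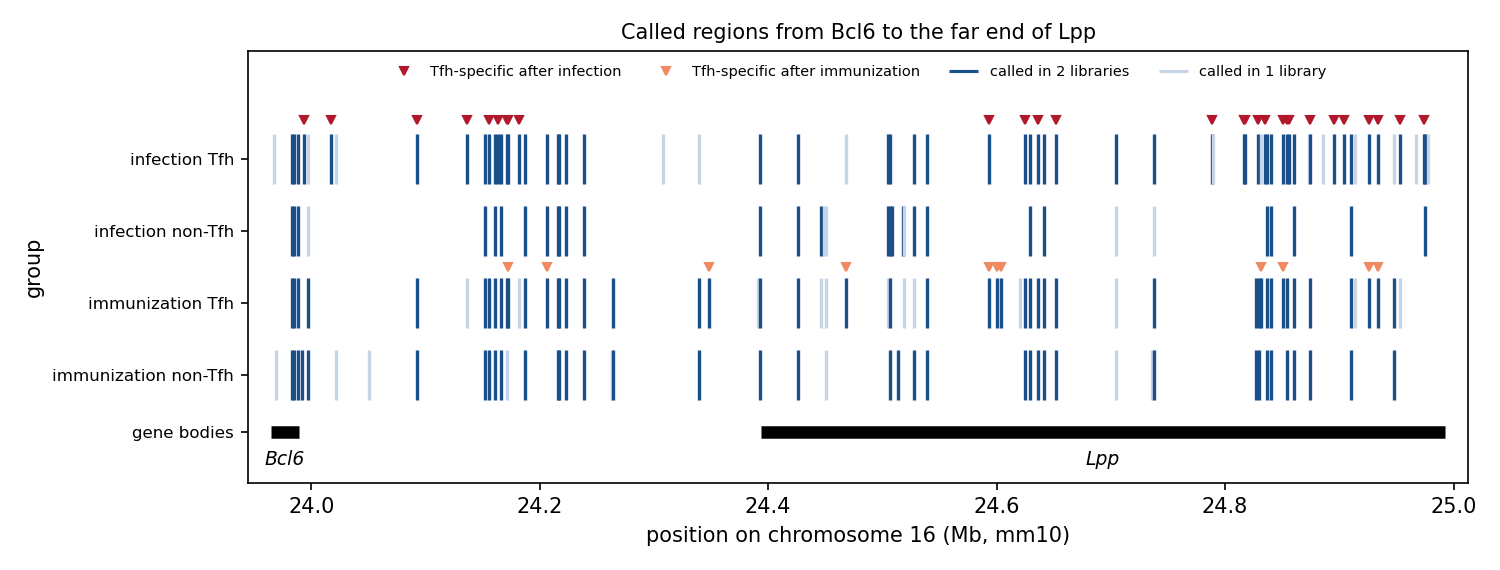
Called regions on chromosome 16 (mm10, position in Mb) from Bcl6 to the far end of Lpp in the 4 groups, dark where both libraries and light where a single library had a peak; triangles mark regions Tfh-specific after infection (28) and after immunization (11), and black bars the gene bodies. Infection non-Tfh cells have the fewest called regions over the downstream part of Lpp.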

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

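Neither the chromosome Y count nor the test of the difference between stimuli was part of the planned comparisons, and both were added after the data were seen. The Th1 and cytotoxic effector program differed between the stimuli in its Tfh against non-Tfh shift. Over the 27 genes with regions under both stimuli, the shift was -9.73% after infection and -1.32% after immunization. The difference of -8.41 percentage points compared with a mean of 13.83 for matched random lists (permutation p = 0.0001, the smallest they can give; adjusted p = 0.0019 over 19 lists). Under the alternatives it was -21.5 to -4.14, with adjusted p of 0.0019 to 0.071, and it did not pass with the 20000 best peaks per library (0.071). No explanation for this difference was tested, and tissue differs along with the stimulus.

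Chromosome Y, which no comparison uses, carried 22 to 25 called intervals in each of the 8 libraries. The lowest count was 22, in infection Tfh replicate 1. Intervals in sequence shared with chromosome X were not separated here, and no explanation was tested.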

How the results depend on the processing

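The 38000 best peaks, the margin and the other background of the overlap were chosen after the results were seen. Stimulus gave the highest pseudo-F under every setting of peaks and regions that was run. With replicate numbers as a block it was 3.33 (exact permutation p = 0.0556, the smallest that block allows) and cell type 1.41 (exact permutation p = 0.167). Correlations between equal numbers were -0.0 to 0.013, so no pairing by number showed in the calls. They cannot exclude that libraries with equal numbers came from the same animals, which is not known here. Specific regions are given in the order infection Tfh and non-Tfh, immunization Tfh and non-Tfh, Tfh after infection and immunization, non-Tfh after infection and immunization, where they moved over 1.5 times. With −log10 q of at least 5, immunization Tfh had 763 and both stimuli 210 (also the shared Tfh count). With the 20000 best peaks, infection Tfh had 2175, immunization Tfh 598 and non-Tfh 584, Tfh after infection 1480, and non-Tfh 2889 and 2785. Over all libraries Tfh then had 124 and infection 538 (immunization 629). With the 38000 best, the infection groups had 4527 and 4050, the Tfh groups 3319 and 2746, all non-Tfh 106 and all immunization 1041 (infection 1033). With the margin these were 5229 and 1495, 444 and 875, and 3814 and 504, and over all libraries Tfh 95, non-Tfh 21, infection 844 and immunization 243. With 50% cover all non-Tfh had 116. Stricter peaks shorten lists by construction, and equal lengths push directions towards balance. Other causes were not tested.

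Leaving out a library raises counts by construction, since a single library then stands for its group. Infection Tfh ranged from 9518 to 12715 (12715 without infection Tfh 1) and non-Tfh from 3040 to 4095 (3761 and 4095 without its replicates 1 and 2). Immunization Tfh ranged from 2073 to 3318 (3044 and 3318 without its own, 2212 without non-Tfh 2) and non-Tfh from 3267 to 4792 (4792 and 4052 without its own, 4128 and 3267 without Tfh). Between Tfh groups the ranges were 7809 to 10893 (10893 without infection Tfh 1) and 1950 to 3073 (2853 and 3073 without immunization Tfh, 2237 without infection Tfh 2), and between non-Tfh groups 5631 to 7178 and 7698 to 9529. Over all libraries Tfh ranged from 356 to 611 (496 and 527 without immunization non-Tfh, 492 and 611 without immunization Tfh) and non-Tfh from 90 to 169 (169 and 121, 102 and 99 in the same order, 99 and 102 without infection non-Tfh, 119 without infection Tfh 2). Infection ranged from 1626 to 1866 and immunization from 625 to 932 (905 without immunization Tfh 2, 932 without infection Tfh 2). The overlap ratio of 1.40 was 1.04 to 1.56 with a library left out. It was 1.68 with −log10 q of at least 5, 1.77 with the margin and 2.29 with the 20000 best peaks. The ratio was 0.695 without regions called in all libraries in the background, which raises the expected number by construction.

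The Th1 and cytotoxic effector calls held in all 13 alternatives, at -25.41 to -7.50% between infection groups and 23.08 to 42.37% between non-Tfh groups (adjusted permutation p at most 0.0074). The B cell call after immunization held in 12 and was 0.0% with the 20000 best peaks, where the NK shift after infection was also 0.0%. For the B cell regions this follows from the setting, as their percentiles were at most 38.1. The NK call was lost in 5 further alternatives, among them leaving out infection non-Tfh replicate 1 (adjusted permutation p = 0.069) or 2 (0.16), over a range of 0.011 to 1.0, while the shifts there were -24.0 and -20.0%, and -34.78% with the 38000 best. Lists that passed after infection numbered 1 instead of 2 with −log10 q of at least 5, the 20000 best, the 38000 best and the margin (1 to 2 with a library left out). After immunization they numbered 1 instead of 2 in each alternative. Between Tfh groups they numbered 0 with −log10 q of at least 5 and with the margin, 3 with 50% cover or summit windows, and 2 with 20 kb, 10 kb or distal regions (1 to 3 with a library left out, 2 without immunization Tfh 1 and 3 without infection Tfh 2). Between non-Tfh groups they numbered 2 with 10 kb. The share of regions called in all libraries near gene ends was 42.0% with −log10 q of at least 5 and 57.4% with the 20000 best, where that of specific regions was 8.04%. Of the counts at named genes, 1226 stayed within 1.5 times and 373 did not. Motif content and its alternatives were not run. Read depth is unknown, so a region not called is not shown to be closed.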

Other observations

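The tests of split counts, list lengths, background and pooled lists of other cell types were chosen after the results were seen, and the Bcl6 to Lpp interval was chosen from its values. Several lists leaned to 1 side without passing, and some passed under alternatives. Between the Tfh groups the Th17 program had 25 infection-specific and 2 immunization-specific regions of 76 (shift 30.26%, random mean 13.44%, adjusted permutation p = 0.097, but 0.022 with 50% cover and 0.03 with summit windows). Its member Rora alone held 14 of the 25 infection-specific and 33 of the 76 accessible regions, so this lean rests largely on 1 gene. Between the infection groups the Th17 program had 26 Tfh-specific and 3 non-Tfh-specific regions of 79 (29.11%, adjusted permutation p = 0.3). Between the immunization groups the Th17 program passed towards Tfh with the 20000 best peaks (29.41%, adjusted permutation p = 0.022). The type I interferon response passed towards infection in Tfh cells without infection Tfh replicate 2 (33.8%, adjusted permutation p = 0.017) and with distal regions only (41.67%, 0.024). Within non-Tfh cells NK cell markers had 7 infection-specific and 0 immunization-specific regions of 24 (29.17%, adjusted permutation p = 0.16), and passed with gene bodies and 10 kb around them (0.048). Chemokine receptors, integrins and homing genes had 21 and 22 of 184 between the infection groups (-0.54%, random mean 12.03%, adjusted permutation p = 0.085), and passed towards non-Tfh with summit windows (0.021).

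Regions at B cell genes were called in immunization Tfh libraries and not in immunization non-Tfh libraries, and a candidate explanation is B cells in the Tfh sort. The shift against non-Tfh cells was not shown to be particular to immunization: over the 10 genes with regions under both stimuli it was 39.13% after infection and 36.11% after immunization (adjusted permutation p = 0.61 for the difference), and with gene bodies and 10 kb around them it passed after infection too (40.91%, adjusted permutation p = 0.048). A second list of 16 B cell and MHC class II genes, with 0 genes of the first, shifted by 21.82% after immunization (random lists -10.71 to 7.41%, permutation p = 0.0001, the smallest they can give), which B cells would produce, and for the MHC class II genes dendritic cells too. After infection the second list shifted by 28.0% and did not pass (random mean 13.3%, adjusted permutation p = 0.11). Between the Tfh groups it shifted towards immunization (-12.07%, random lists 1.72 to 24.14%, adjusted permutation p = 0.0004), as the first list did (-30.95%). The 18 regions of the first list were weak, with a median percentile of 18.1 in their lists and a highest of 38.1, against 17.0 for the other 1391 Tfh-specific regions. NK, erythroid, stromal and myeloid genes together shifted by 6.10% (bootstrap 95% interval -1.33 to 14.3%), less than the 42.5% of the first B cell list. The single lists were known when they were pooled, so this describes them and is no test of all cell types entering alike. It also cannot address cells that enter in proportion to their numbers. The tables argue against longer Tfh lists, since the longer immunization Tfh list held 39907 intervals and the shorter non-Tfh list 40792. Myeloid and dendritic genes alone shifted by 13.33%, so such cells stay open beside B cells. The B cell shift was 55.56% with the 38000 best peaks, and 0.0% with the 20000 best, which leave out such weak regions by construction. Sorting for donor CD45.2 would remove host B cells but the gates are not given, and accessibility of these genes in the Tfh cells themselves stays open and untested.

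Infection Tfh cells had more specific regions than infection non-Tfh cells. Deeper sequencing of the Tfh libraries is not decided: the background pileup overlapped (1.955 and 1.782 against 1.760 and 1.877), and per 100 bp, taking the shortest peak as the fragment length, it was 0.977 and 0.963 against 0.903 and 0.953. The immunization libraries had 0.972 to 1.129 with shorter lists, so background and list length did not go together across groups. List length and biology cannot be told apart: with the 38000 best peaks the Tfh share was 52.8%, but equal lengths push it towards balance. A larger accessible genome in infection Tfh cells may remain among the open explanations.

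The excess of Tfh-specific over non-Tfh-specific regions from Bcl6 to the far end of Lpp was 25 after infection, where 1 of 931 equally long windows was as large (highest 28), and 9 after immunization, where 0 of 819 were (highest 6). The interval was chosen because Lpp led these same counts. Its high rank among windows follows largely from that choice and is no independent support. With the 20000 best peaks, the Tfh-specific regions fell from 28 to 7 after infection and from 11 to 4 after immunization. Of the 11 Tfh-specific regions after immunization, 6 (54.5%, exact 95% interval 23.4 to 83.3%) were called in both infection Tfh libraries. This does not separate B cells in the sort from Tfh cells, since B cell markers also had 9 Tfh-specific and 0 non-Tfh-specific regions after infection. Use of this interval in Tfh cells under both stimuli may be a biological explanation and stays a hypothesis beside it.

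For the 379 cell-type regions, chance is not excluded: 2 of the 35 splits of the 8 libraries gave as many, and the highest other split, with 2072, was the split by stimulus. As stimulus is the other factor of the design, its larger count kept this test from excluding chance for cell type. For the 2072 stimulus regions, 1 of the 35 splits, the real one, gave as many, and the highest other was 379, so chance is excluded at a share of 0.0286 only if the 8 libraries are independent. Of the 35 splits, 3 keep replicates together, and they gave 2072, 379 and 262 regions, above the highest of the others (148). If replicates are technical, these 3 are too few to exclude chance, and tissue stays joined to stimulus.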
